A study of Rattus norvegicus with 15 samples.

How the data were processed

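Total RNA of rat uterus (TRNzol extraction and Fast RNA-seq Lib Prep Kit V2, per the labels' protocols) was sequenced in 15 samples, 3 in each of 5 groups, on day 14. The authors deposited one table of raw counts of reads per gene, with 1 column per sample and no normalization. HISAT2, featureCounts, DESeq2 and the build mRatBN7.2 are named in the submitters' processing notes; their versions and the role of each are not given in the sources used here. The strand setting, the annotation release and the handling of reads with several alignments are not stated either, so counts of near-identical genes (the RT1 family, haemoglobins, Mx and Cyp2d genes) are those of whichever copies the reads were given to. The values are whole numbers that sum to different totals, and 0 sample columns were left without a group.

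Groups were read from the abbreviations in the sample titles together with the series design, as sham surgery (con), injury (model), gelatin hydrogel (gel), hydrogel with stem cells (mensc) and hydrogel with stem cell spheroids (sp). Replicates are numbered in order within a group, and the numbers carry no pairing. The labels give no batch, date, sex, age or stage of the oestrous cycle. Symbols of 27234 genes matched a reference table of rat RefSeq genes, and 99.5% of neighbouring matched genes lay on one chromosome, so the table runs in genomic order. Of 358 list genes, 354 were in the table, and no gene is in more than 1 list.

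Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on group (minimum count 10), which left 16689 of 34322, libraries were scaled by TMM, and 1 quasi-likelihood model of 5 groups was fitted with robust dispersion estimates. Each of 10 comparisons was a contrast of this fit, and a test of any difference among the 5 groups was made in the same fit. Values of p were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05. Two-sided tests were used throughout. A comparison of 3 against 3 single values cannot go below an exact permutation p of 0.1, so single values were not tested that way. Fold changes are given as log2 with their SE, and levels as TMM-scaled CPM with their SD.

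Gene lists were written for cell division, MHC class II, interferon response, fibrosis and matrix, matrix proteases, inflammatory cytokines, macrophages, neutrophils, T and NK cells, B and plasma cells, eosinophils and mast cells, epithelium, ciliated epithelium, squamous epithelium, stroma, smooth muscle, skeletal muscle, endothelium, angiogenic factors, mesothelium, adipose tissue and blood. The others were oestrogen-responsive genes, progesterone and receptivity genes, hypoxia and glycolysis, and immediate early genes. The 26 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. Adjustment was over the 26 lists of a comparison. A list score is the mean over members of the log2 CPM minus the gene's mean over 14 libraries, and the share of its variance between groups was tested with 100000 permutations of the library labels. Counts adjusted over the list alone apply Benjamini-Hochberg to edgeR's p of the list's members.

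The rule for named genes was, among genes past the threshold with a symbol, an average log2 CPM of at least 1 and no overlap in CPM between the groups' libraries, to take the largest rises and falls. Where fewer than 4 genes passed, the rule gives the 4 genes with the smallest p that meet the other criteria, as values that did not pass, and this applied to all 10 comparisons. For each list described, up to 4 members with the smallest p are given. Not every gene that the rule gives is described. Genes named because DESeq2 called them were picked out after their values were seen. The groups, the comparisons, the tests, the lists, this rule and the first set of other settings were fixed before the data were examined.

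The first set of other settings was DESeq2 1.42.0, relative log expression size factors, no filter on low counts, an average log2 CPM of at least 1, only the 6 libraries compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. Chosen after the data were examined were DESeq2 without model replicate 2, list tests without model replicate 2, 2 surrogate variables (sva 3.50.0) without model replicate 2, only genes ahead of the run of zeros, separate model libraries for the fold changes of injury and repair, and the permutation of list scores. Principal components were computed on log2 CPM of 12374 genes ahead of the run of zeros, and the loadings of a list were compared with 10000 random lists matched on expression. The edgeR procedure was tested on simulated counts with 100 genes seeded at 2-fold and 100 at 4-fold. Nothing was left out of the planned fit.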

Results

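RNA from rat uterus was sequenced in 15 libraries, with 3 in each of 5 groups, on day 14. Per the series design, con had sham surgery, model carried a physical injury of the endometrium, and the other groups carried the injury and a repair. Gel received gelatin hydrogel, mensc the hydrogel with human menstrual blood-derived mesenchymal stem cells, and sp the hydrogel with spheroids of those cells. Total counts over 34322 genes were 15584386, 25728326 and 16221946 in con, 17653788, 13166540 and 15182337 in model, and 17807418, 17313967 and 17709001 in gel. They were 21592481, 19610641 and 15820420 in mensc and 16832285, 15745893 and 16381224 in sp. Replicates of a group differed by far more than counting error, with a chi-square of at least 30.0 per degree of freedom between any pair. The labels do not say that replicates are separate animals, so each p measures the spread between these samples.

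Model replicate 2 holds counts for only part of the gene table. From Chit1 to the end of the table, 9514 genes in a row read 0 in this library, and Btg2 is the last gene with counts. All 3788 expressed genes in that run (mean of at least 20 counts in the other 14 libraries) were at 0, against 27 of 10894 expressed genes, 0.248%, ahead of it. Col6a1, Col6a2 and Tmsb4x, at means of 81444.5, 77084.4 and 68191.8 counts in the other libraries, were among those at 0. In the other 14 libraries the run held between 24.4% and 25.6% of the counts. The run holds 4315 of the 16689 genes tested, so a fold change against model for these genes mixes 2 libraries with counts and 1 without. All groups share 1 estimate of each gene's spread, so the zeros also enter the tests of these genes in comparisons without model. The common coefficient of variation between libraries of a group was 0.607 in the planned fit and 0.432 without model replicate 2. Genes chosen by the rule for single genes lie ahead of the run and are given from the planned fit of 15 libraries, and values from DESeq2 are named as such. Gene lists span it and are given from a fit without model replicate 2, a choice made after the data were examined, with the number of lists called in the planned fit beside them.

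**Figure D1:**
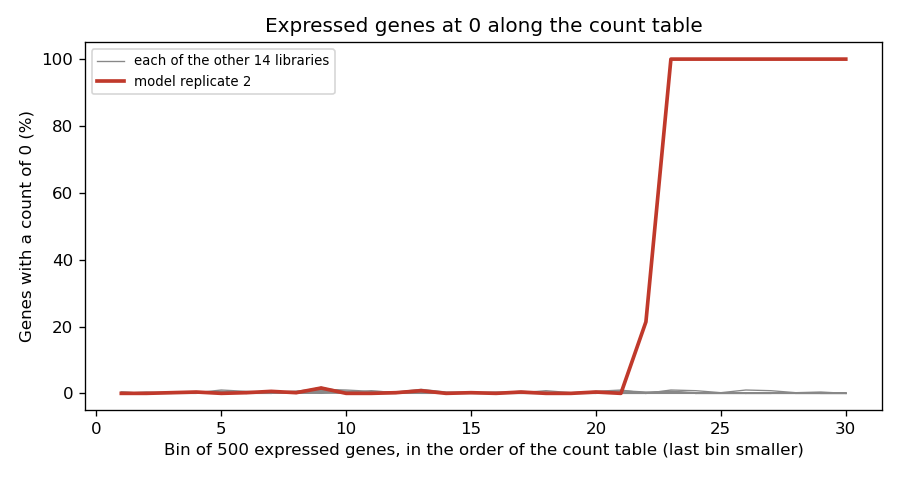
Percent of expressed genes at 0 counts (y axis) in successive bins of 500 expressed genes in table order (x axis), for each of the 15 libraries. Model replicate 2 goes from 0.248% ahead of the run to 100% within it, while the other 14 libraries stay near 0.

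The largest differences between libraries ran across the groups. The first principal component held 35.8% of the variance of 12374 genes ahead of the run, and con, model, mensc and sp each had libraries on both sides of it. Con replicates 1 and 2, model replicate 3, mensc replicates 1 and 2 and sp replicate 1 lay on the negative side, from -63.1 to -37.2. The other 9 libraries lay on the positive side, from 14.8 to 73.4, with all 3 of gel among them. Aqp8, a water channel, ranged from 0.615 to 3.07 CPM in the 6 libraries and from 36.0 to 420 CPM in the 9. Oxtr, the oxytocin receptor, ranged from 2.73 to 15.0 CPM in the 6 and from 66.1 to 241 CPM in the 9. Pamr1 went the other way, with 136 to 393 CPM in 5 of the 6 libraries, 29.4 CPM in sp replicate 1 and 2.60 to 14.8 CPM in the 9. These genes were picked out after their values were seen. Sp replicate 2 stood apart on the second component, which held 17.2% of the variance.

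**Figure D2:**
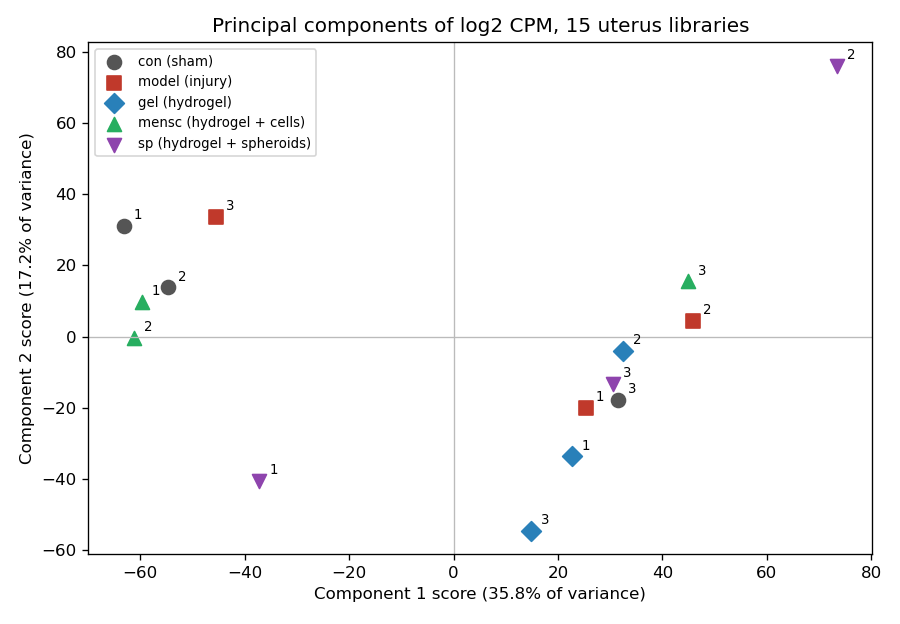
Scores of the 15 libraries on the first principal component (x axis, 35.8% of the variance) and the second (y axis, 17.2%) of log2 CPM of genes ahead of the run of zeros, coloured by group. Con, model, mensc and sp each have libraries on both sides of 0 on the first component, and sp replicate 2 has the highest score on the second, 76.2.

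**Figure D3:**
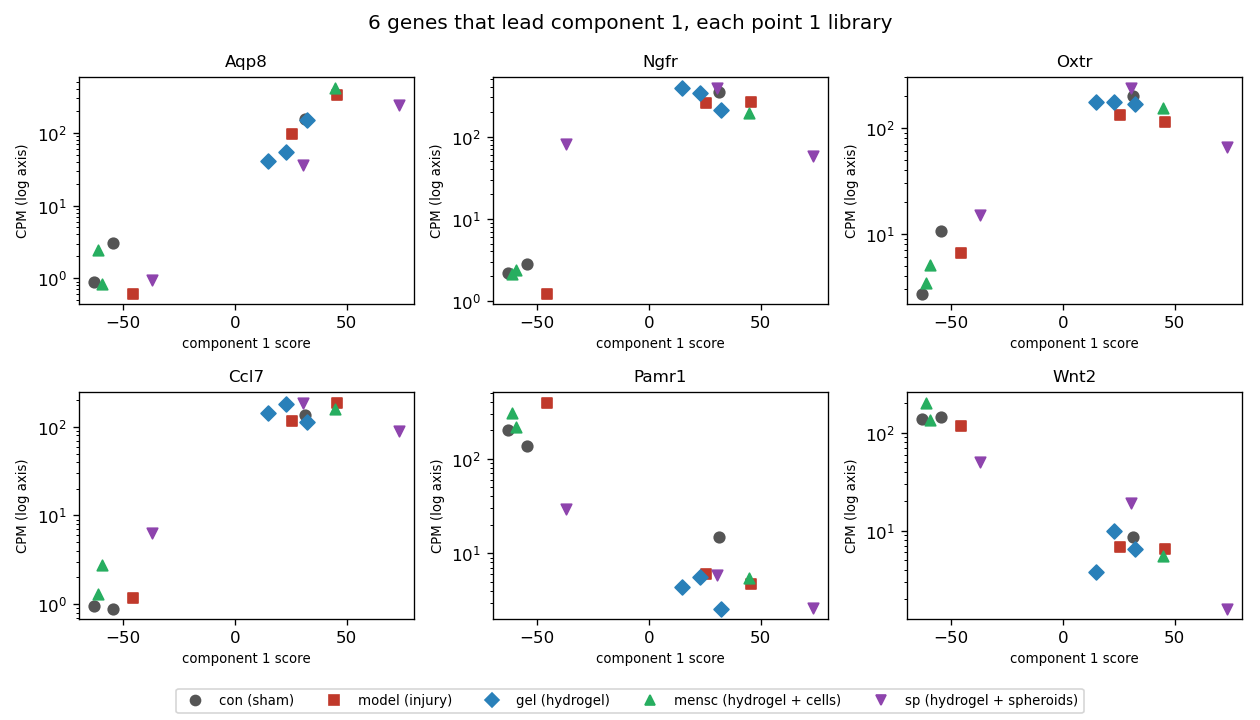
CPM (y axis, log scale) of Aqp8, Ngfr, Oxtr, Ccl7, Pamr1 and Wnt2 against the score on the first principal component (x axis), one point per library, coloured by group. Aqp8 lies at or below 3.07 CPM in the 6 libraries of the negative side and at or above 36.0 CPM in the 9 of the positive side.

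Across all 5 groups at once, edgeR called 0 of 16689 genes at a Benjamini-Hochberg adjusted p under 0.05, with 607 at an unadjusted p under 0.05. The gene nearest to a call was Doc2b, a calcium sensor of vesicle exocytosis, at an adjusted p of 0.0619 in edgeR. Without model replicate 2 it was called (adjusted p = 0.0466 in edgeR), as the only gene of 17071 tested, and 979 genes had an unadjusted p under 0.05. Without gel replicate 3 it was Iho1, a protein of meiotic chromosomes, that was called (adjusted p = 0.0237 in edgeR). DESeq2 called 139 genes on the 15 libraries and 172 without model replicate 2. The shares of tested genes that follow include the 4315 genes of the run, at 0 in model replicate 2. Such a gene could fail to overlap in a comparison with model only with model lower. The share of tested genes whose CPM did not overlap between the groups compared, where chance gives 10%, was 7.65% in model vs con, 11.8% in gel vs model, 6.55% in mensc vs model and 7.92% in sp vs model. It was 16.2% in mensc vs gel, 13.3% in sp vs gel, 11.8% in sp vs mensc, 17.0% in gel vs con, 4.22% in mensc vs con and 11.8% in sp vs con. In simulated data of this layout, without a run of zeros and with independent genes, the edgeR test recovered 4% to 17% of 2-fold changes and 53% to 66% of 4-fold changes. The changed genes had a mean of at least 2 CPM, and the spread was that of the fit without model replicate 2. Recovery in the planned fit, where the spread was larger, and for genes with fewer counts may be lower.

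Among 26 gene lists, those for cell division and MHC class II differed most between groups. Cell division scores (mean log2 deviation of 21 genes) averaged 0.77 ± 0.61 in sp and 0.68 ± 0.54 in gel, against -0.60 ± 0.52 in con and -0.66 ± 0.14 in mensc (SD, n = 3). The 2 usable model libraries averaged -0.28. MHC class II scores (8 genes) averaged -1.10 ± 0.45 in sp, against 0.28 ± 0.44 in con, 0.57 ± 0.73 in gel and 0.43 ± 0.70 in mensc, and -0.26 over 2 libraries in model. Group explained 70.9% of the variance of the cell division score and 65.9% of that of MHC class II, at permutation p of 0.0226 and 0.0317 over 14 libraries. Adjusted over the 26 lists, the permutation p was 0.412 for both. Cell division genes also followed the first principal component, with 19 of 19 members ahead of the run loading on its positive side, where all 3 gel libraries, 2 of 3 sp, 1 of 3 con and 1 of 3 mensc libraries lay. Within that, mensc replicate 3 on the positive side had a cell division score of -0.81 and sp replicate 1 on the negative side one of 0.11. Sp replicate 2 had all 21 members above their mean in the other 13 libraries, by 1.39 ± 0.08 (mean, SE over members in that library). The epithelial list stood at the other end, with 1.09% of its variance between groups (permutation p = 0.998, the same after adjustment). Its lowest and highest scores of the 14 libraries were both in sp, -1.47 in replicate 1 and 1.54 in replicate 2.

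In 260 tests of a list in a comparison, camera at its preset correlation of 0.01 called 52 without model replicate 2 and 42 in the planned fit. With an estimated correlation camera called 0 in either fit, with a smallest adjusted p of 0.384 without model replicate 2, and fry also called 0, with a smallest adjusted p of 0.0850. Of the 52 calls, 15 were kept without each further library of the compared groups in turn. Over all genes, edgeR called 0 list members in any comparison, and adjusted over the list alone 109 members passed without model replicate 2 and 76 in the planned fit. Without model replicate 2, camera called 9 of the 26 lists in no comparison, and for each of these the smallest adjusted p over the 10 comparisons in that fit follows. It was 0.109 for progesterone and receptivity genes and 0.101 for matrix proteases (both sp vs model), and 0.387 for epithelium and 0.125 for angiogenic factors (both sp vs gel). For ciliated epithelium, neutrophil and squamous genes it was 0.0731, 0.0525 and 0.321, each in model vs con, for hypoxia and glycolysis 0.278 in mensc vs gel, and for skeletal muscle 0.160 in gel vs model.

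**Figure D4:**
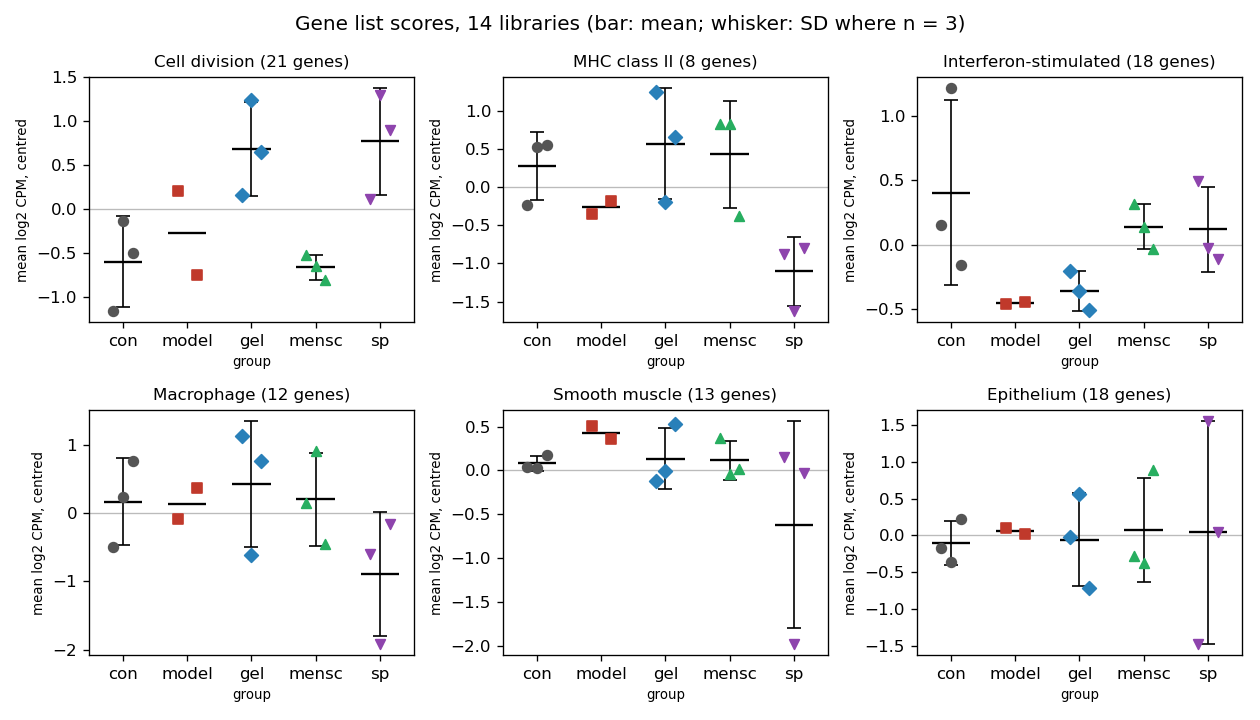
Mean log2 deviation of the members of 6 gene lists (y axis) in each of 14 libraries by group (x axis), with the group mean as a line and the SD as a bar where n = 3. The 3 sp libraries have the lowest MHC class II scores, -1.62, -0.87 and -0.80, and sp and gel have the highest mean cell division scores, 0.77 and 0.68.

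The injury itself is addressed by model vs con. Interferon-response genes were lower in model, with all 18 members below con at a mean log2 fold change of -0.86 ± 0.56 (SD over members, camera adjusted p = 1.26e-09; adjusted p = 0.492 with an estimated correlation). The antiviral genes Mx2, Mx1, Rsad2 and Ifit3 had values of -1.33 ± 0.35, -1.45 ± 0.40, -2.03 ± 0.83 and -1.39 ± 0.53 (SE). Fibrosis and matrix genes were higher, 17 of 20 at a mean of 0.65 (adjusted p = 0.00643; adjusted p = 0.814 with an estimated correlation), with Tnc (tenascin C) at 3.48 ± 1.26 and Ccn2 at 1.57 ± 0.96 (SE). Cell division genes were higher in 20 of 21 members, at a mean of 0.33 (adjusted p = 0.00875), and MHC class II genes lower in 8 of 8, at -0.54 (adjusted p = 0.0224). With an estimated correlation the adjusted p was 0.814 for both.

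Adjusted over the list alone, 2 interferon-response members passed and 0 of the other 3 lists, against 0 over all genes in edgeR. Camera called 4 lists in model vs con here and 3 in the planned fit, where fibrosis and matrix genes had a mean of -0.22 and a median of 0.30 and were not called (camera adjusted p = 0.191). Con replicate 2 had the highest interferon score of the 14 libraries, 1.22, and without it the mean was -0.45. The fibrosis and matrix call ended without model replicate 3 (mean 0.17) or con replicate 1 (0.54), and the mean was 1.15 without model replicate 1. Cell division lost its call without con replicate 1 (0.05), con replicate 3 (0.38) or model replicate 1 (-0.15), and stood at 0.56 without con replicate 2 and 0.81 without model replicate 3, while MHC class II lost it without con replicate 3 (-0.41), model replicate 1 (-0.46) or model replicate 3 (-0.62). Camera also called MHC class II lower in the planned fit, at a mean of -3.37, but that fit holds the zeros of model replicate 2.

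No single gene passed in model vs con by edgeR, 0 of 16689 with 367 at an unadjusted p under 0.05 (331 without model replicate 2). DESeq2 called 2 on the 15 libraries and 0 without model replicate 2. The 2 were the uncharacterised loci LOC500166 (lower) and LOC103690146 (higher), named after their values were seen. Cldn16, a tight-junction claudin, stood at 10.1 ± 7.33 CPM in model and 2.07 ± 0.675 CPM in con (SD, n = 3), a log2 fold change of 2.29 ± 0.64 (SE, edgeR adjusted p = 0.976). Cdca4 was at 0.66 ± 0.20, and Amhr2, the receptor of anti-Müllerian hormone, at -2.72 ± 0.79 (SE, both at an edgeR adjusted p of 0.976). Without model replicate 3, at 18.5 CPM against 5.05 and 6.78 in the other two, Cldn16 was at 1.47, and without con replicate 1 Amhr2 was at -1.79.

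The hydrogel alone is addressed by gel vs model. Cell division genes were higher in gel in 21 of 21 members, at a mean log2 fold change of 0.96 ± 0.35 (SD over members, camera adjusted p = 1.53e-12; adjusted p = 0.912 with an estimated correlation). The replication genes Mcm2, Pcna and Mcm3 were at 0.70 ± 0.26, 0.59 ± 0.25 and 1.09 ± 0.39 (SE). MHC class II genes were higher in 8 of 8 members, at a mean of 0.83 (adjusted p = 0.00121; adjusted p = 0.912 with an estimated correlation), with Ciita, the class II transactivator, at 0.75 ± 0.45 and RT1-Ba at 1.07 ± 0.54 (SE). Camera called these 2 lists in gel vs model, and 2 in the planned fit, and 0 members passed adjusted over the list alone or over all genes. Without model replicate 3 the cell division mean was 0.49, and the MHC class II call ended without model replicate 1 (0.74) or gel replicate 1 (0.49). In the planned fit, which holds the zeros of model replicate 2, the MHC class II mean was 3.68. That call is thus no separate support for the one here.

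Among single genes in gel vs model, edgeR called 0 of 16689, with 338 at an unadjusted p under 0.05 (624 without model replicate 2). DESeq2 called 6 on the 15 libraries and 5 without model replicate 2. Those 5 were Iho1, Aldh1a1, Sectm1b, Ces2a and LOC500166, the last 3 of them named after their values were seen. Cldn16 stood at 1.82 ± 0.910 CPM in gel against 10.1 ± 7.33 in model (SD, n = 3), a log2 fold change of -2.47 ± 0.64 (SE, edgeR adjusted p = 1.00). Aldh1a1, a retinaldehyde dehydrogenase, was at -2.61 ± 0.70 (SE), and at -1.19 without model replicate 3, which held 100 CPM against 18.9 and 15.2 in the other two. Iho1 was at 4.69 ± 1.00 (SE), from 17.4 and 21.2 CPM in gel replicates 1 and 2 but 0.896 CPM in gel replicate 3.

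The hydrogel with dispersed cells is addressed by mensc vs model. B and plasma cell genes were higher in mensc in 10 of 10 members, at a mean log2 fold change of 1.36 ± 0.83 (SD over members, camera adjusted p = 8.11e-05; adjusted p = 0.759 with an estimated correlation). Cd79b, part of the B cell receptor, was at 3.13 ± 1.05, and Jchain, the joining chain of IgA and IgM, at 2.75 ± 1.53 (SE). MHC class II genes were higher in 8 of 8, at a mean of 0.69 (adjusted p = 0.000544; adjusted p = 0.899 with an estimated correlation), with Cd74, the invariant chain, at 1.22 ± 0.46 and Ciita at 1.01 ± 0.45 (SE). Cell division genes were lower in 21 of 21, at -0.39 (adjusted p = 0.000550), and fibrosis and matrix genes in 17 of 20, at -0.57 (adjusted p = 0.00768), each at an adjusted p of 0.899 with an estimated correlation. Interferon-response genes were higher in 17 of 18, at 0.59 (adjusted p = 0.00306), and T and NK cell genes in 15 of 17, at 0.43 (adjusted p = 0.0445). With an estimated correlation the adjusted p was again 0.899 for both.

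Camera called 6 lists in mensc vs model and 3 in the planned fit, where fibrosis and matrix genes had a mean of 0.30 and a median of -0.20 and were not called (camera adjusted p = 0.326). In the fit without model replicate 2, 0 members passed adjusted over the list alone or over all genes. Without mensc replicate 3 the B and plasma cell mean was 2.05, MHC class II 1.09 and T and NK cells 0.98, and the calls of cell division (-0.31), interferon response (0.68) and fibrosis and matrix (-0.51) ended. Without model replicate 1, cell division (0.09), interferon response (0.59) and T and NK cells (0.58) lost their calls and fibrosis and matrix stood at -1.06. Without model replicate 3, fibrosis and matrix (-0.08) and T and NK cells (0.28) lost theirs and cell division stood at -0.87. T and NK cells also lost their call without mensc replicate 1 (0.15) or 2 (0.17), while B and plasma cells and MHC class II kept theirs without each further library. Mensc replicate 3 did not share these rises. Its B and plasma cell score was -0.59, against -0.57 and -0.60 in model replicates 1 and 3. Its MHC class II score was -0.38, against -0.35 and -0.18. Among the 5 groups the permutation p of the B and plasma cell score was 0.300.

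Single genes in mensc vs model gave 0 calls of 16689 by edgeR, with 310 at an unadjusted p under 0.05 (296 without model replicate 2). DESeq2 called 5 on the 15 libraries and 3 without model replicate 2. The 3 were Doc2b and the uncharacterised loci LOC500166 and LOC102549024, and the 5 also held Abcc10 and Unkl, all but Doc2b named after their values were seen. Doc2b stood at 16.2 ± 5.54 CPM in mensc and 4.15 ± 0.795 in model (SD, n = 3), a log2 fold change of 1.97 ± 0.37 (SE, edgeR adjusted p = 0.988). Kntc1, a kinetochore protein, was at -1.46 ± 0.40, Cldn16 at -2.19 ± 0.64 and Amotl2 at -0.90 ± 0.27 (SE, each at an edgeR adjusted p of 0.988), with Cldn16 at -1.35 without model replicate 3.

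The hydrogel with spheroids is addressed by sp vs model. Cell division genes were higher in sp in 21 of 21 members, at a mean log2 fold change of 1.04 ± 0.37 (SD over members, camera adjusted p = 5.19e-14; adjusted p = 0.554 with an estimated correlation), with the mitotic genes Ccnb2, Bub1 and Aurkb at 1.26 ± 0.59, 1.25 ± 0.51 and 1.25 ± 0.56 (SE). Smooth muscle genes were lower in 13 of 13, at -1.05 (adjusted p = 4.05e-06; adjusted p = 0.554 with an estimated correlation), with Des (desmin) at -1.98 ± 0.54 (SE). Fibrosis and matrix genes were lower in 19 of 20, at -1.14 (adjusted p = 1.43e-05; adjusted p = 0.554 with an estimated correlation), with Thbs1 at -2.69 ± 0.84 and Ccn2 at -2.53 ± 0.97 (SE). Macrophage genes were lower in 12 of 12, at -1.03 (adjusted p = 8.18e-05), and MHC class II genes in 8 of 8, at -0.84 (adjusted p = 0.00207). With an estimated correlation the adjusted p was 0.554 for both. Interferon-response genes were higher in 14 of 18, at 0.57 (adjusted p = 0.0226; adjusted p = 0.643 with an estimated correlation), and endothelial genes lower in 12 of 13, at -0.35 (adjusted p = 0.0461; adjusted p = 0.713 with an estimated correlation).

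In the planned fit, which holds the zeros of model replicate 2, camera called 5 lists in sp vs model against 7 here, and some signs differed. MHC class II genes had a mean of 2.01 there, higher in 7 of 8 members (camera adjusted p = 0.475), endothelial genes a mean of 0.25 and a median of -0.21 (0.220), and macrophage genes, called lower (0.0210), a mean of 0.02 and a median of -0.88. Neutrophil genes were called in that fit only, lower in 7 of 8 members at -0.69 (camera adjusted p = 0.0450; adjusted p = 0.953 with an estimated correlation), and lost the call without model replicate 1 (-0.11), model replicate 2 (-0.78) or sp replicate 2 (-0.07), with -1.14 without model replicate 3. The neutrophil call also ended in the planned fit with an average log2 CPM of at least 1 (-0.75, camera adjusted p = 0.112). Without model replicate 2, adjusted over the list alone 1 member passed, Des, against 0 over all genes. The cell division call was kept without each further library, though the score of model replicate 1, 0.20, lay above that of sp replicate 1, 0.11. Without sp replicate 2 the calls of smooth muscle (-0.37), fibrosis and matrix (-0.48), macrophage (-0.52), MHC class II (-0.58), interferon response (0.65) and endothelium (0.05) ended. Without model replicate 1, MHC class II (-0.92), interferon response (0.56) and endothelium (-0.06) lost their calls, and without sp replicate 1 interferon response did (0.38) while endothelium stood at -0.61. Without model replicate 3 cell division stood at 0.55, fibrosis and matrix at -0.66 and endothelium at -0.66.

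For single genes in sp vs model, edgeR called 0 of 16689, with 430 at an unadjusted p under 0.05 (696 without model replicate 2). DESeq2 called 10 on the 15 libraries and 11 without model replicate 2. Cd8a, a T cell coreceptor, stood at 37.4 ± 14.3 CPM in sp and 12.0 ± 1.76 in model (SD, n = 3), a log2 fold change of 1.64 ± 0.36 (SE, edgeR adjusted p = 0.997). Col6a6, a collagen VI chain, was at 1.97 ± 0.45, Hrct1 at -1.35 ± 0.30 and Mybpc2 at -1.65 ± 0.40 (SE, each at an edgeR adjusted p of 0.997).

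What dispersed cells add to the hydrogel is addressed by mensc vs gel. Cell division genes were lower in mensc in 21 of 21 members, at a mean log2 fold change of -1.35 ± 0.49 (SD over members, camera adjusted p = 5.70e-21; adjusted p = 0.563 with an estimated correlation). The G1/S cyclin Ccne1 was at -2.46 ± 0.57, and the replication genes Pcna, Mcm2 and Mcm4 at -0.95 ± 0.22, -0.94 ± 0.23 and -1.02 ± 0.27 (SE). Adjusted over the list alone 19 of the 21 passed, against 0 over all genes in edgeR, and DESeq2 called 4 of them without model replicate 2: Ccne1, Pcna, Rrm2 and Mcm5. The call held without each further library, and camera called 1 list in mensc vs gel and 3 in the planned fit. The other 2 there were interferon response, higher in 15 of 18 members at 0.47 (camera adjusted p = 0.0216), and mesothelium, higher in 6 of 7 at 0.94 (0.0344), both at an adjusted p of 0.941 with an estimated correlation, with 0 members passing adjusted over the list alone. Interferon response lost the call without model replicate 2 (0.50), gel replicate 2 (0.50), gel replicate 3 (0.42) or mensc replicate 3 (0.59), and mesothelium without model replicate 2 (0.96), gel replicate 1 (0.58), gel replicate 2 (0.88), mensc replicate 2 (0.84) or mensc replicate 3 (0.98), with 1.43 without gel replicate 3.

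Doc2b came nearest to a call among single genes of mensc vs gel, at 16.2 ± 5.54 CPM in mensc and 1.94 ± 0.606 in gel (SD, n = 3), a log2 fold change of 3.06 ± 0.39 (SE, edgeR adjusted p = 0.0782). It was called when only genes ahead of the run were tested (adjusted p = 0.0250 in edgeR) and with 2 surrogate variables (adjusted p = 0.0277 in edgeR), both choices made after the data were examined. Cdc45, a replication factor, was at -2.25 ± 0.45, Kntc1 at -1.93 ± 0.40 and Topbp1, a checkpoint protein, at -0.85 ± 0.18 (SE, each at an edgeR adjusted p of 1.00). In the planned fit edgeR called 0 of 16689 genes, with 699 at an unadjusted p under 0.05 (1082 without model replicate 2). DESeq2 called 37 on the 15 libraries and 54 without model replicate 2, 20 higher and 34 lower. Egln3, a prolyl hydroxylase of the hypoxia response, was among the 54 at 2.14 ± 0.53 (SE, DESeq2 adjusted p = 0.0329).

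What spheroids add to the hydrogel is addressed by sp vs gel. MHC class II genes were lower in sp in 8 of 8 members, at a mean log2 fold change of -1.67 ± 0.55 (SD over members, camera adjusted p = 8.16e-10; adjusted p = 0.384 with an estimated correlation), with Ciita at -1.59 ± 0.40 and RT1-Ba at -2.18 ± 0.49 (SE). Macrophage genes were lower in 12 of 12, at -1.32 ± 0.20 (SD over members, adjusted p = 5.25e-07; adjusted p = 0.579 with an estimated correlation), with the complement gene C1qa at -1.72 ± 0.60 and the lysosomal protein Cd68 at -1.45 ± 0.39 (SE). Adipose genes were lower in 10 of 10, at -1.97 ± 1.22 (SD over members, adjusted p = 0.000137; adjusted p = 0.579 with an estimated correlation), with Cfd (adipsin) at -2.52 ± 0.85 (SE). Adjusted over the list alone 8 MHC class II, 4 macrophage and 0 adipose members passed, against 0 over all genes in edgeR, and DESeq2 called RT1-Ba without model replicate 2. Camera called 14 lists in sp vs gel and 10 in the planned fit, and these 3 kept their calls without each further library, with the macrophage mean at -0.81 without sp replicate 2. Scores of 2 of the lists overlapped between the groups. The macrophage score was -0.61 in gel replicate 2, against -0.60 and -0.16 in sp replicates 1 and 3. The adipose score was -0.19 in gel replicate 1, against 0.07 in sp replicate 3. Among the 5 groups the permutation p was 0.322 for macrophage and 0.508 for adipose scores.

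The other 11 calls of sp vs gel ended without 1 or more libraries. Lower in sp were smooth muscle at -0.75 (camera adjusted p = 0.000208), endothelium at -0.55 (0.000208) and eosinophil and mast cells at -1.32 (0.0164), each at an adjusted p of 0.579 with an estimated correlation. Inflammatory cytokines were at -0.81 (camera adjusted p = 0.0146) and fibrosis and matrix at -0.62 (0.0146), with adjusted p of 0.384 and 0.588 with an estimated correlation. Stroma was at -0.56 (camera adjusted p = 0.0398), T and NK cells at -0.65 (0.0423) and blood at -1.03 (0.0454), with adjusted p of 0.595, 0.646 and 0.595 with an estimated correlation. Oestrogen-responsive genes were at -0.71 and immediate early genes at -0.44 (camera adjusted p = 0.0454 for both; 0.588 and 0.579 with an estimated correlation), and interferon-response genes were higher at 0.48 (0.0208; 0.588). Of these lists, T and NK cells had 1 member past the threshold adjusted over the list alone, Cd8a, which went against the list at 1.54 ± 0.36 (SE), and the other 10 had 0.

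Without sp replicate 2 the calls of smooth muscle (-0.07), endothelium (-0.15), eosinophil and mast cells (-0.43), fibrosis and matrix (0.04), stroma (0.11), T and NK cells (-0.18), blood (0.01), immediate early (-0.40) and interferon response (0.55) ended, and oestrogen-responsive genes stood at -1.09. Without sp replicate 1 those of oestrogen-responsive (-0.07), immediate early (-0.33) and interferon-response genes (0.29) ended, while smooth muscle stood at -1.14, fibrosis and matrix at -1.05, stroma at -0.98, T and NK cells at -1.02 and blood at -1.66. Leaving out gel replicate 1 ended those of inflammatory cytokines (-0.64), fibrosis and matrix (-0.54), eosinophil and mast cells (-1.18), stroma (-0.46), T and NK cells (-0.33) and oestrogen-responsive genes (-0.66). Leaving out gel replicate 2 ended those of interferon response (0.48), oestrogen-responsive (-0.58) and immediate early genes (-0.34), with eosinophil and mast cells at -2.12, T and NK cells at -1.19 and blood at -1.67. Leaving out gel replicate 3 ended those of eosinophil and mast cells (-0.71), stroma (-0.44), T and NK cells (-0.42) and blood (-0.32).

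In sp vs gel edgeR called 0 of 16689 single genes, with 672 at an unadjusted p under 0.05 (1009 without model replicate 2). DESeq2 called 16 on the 15 libraries and 23 without model replicate 2. Ggn stood at 1.62 ± 0.374 CPM in sp and 5.44 ± 0.554 in gel (SD, n = 3), a log2 fold change of -1.74 ± 0.35 (SE, edgeR adjusted p = 1.00). Rassf4 was at -1.21 ± 0.26, Hrct1 at -1.37 ± 0.30 and Iho1 at -4.42 ± 0.99 (SE, each at an edgeR adjusted p of 1.00), and Cd8a was called by DESeq2 without model replicate 2, at 1.53 ± 0.38 (SE, DESeq2 adjusted p = 0.0437).

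The form in which the cells were given is addressed by sp vs mensc, and here a gene passed. Doc2b was lower in sp, at 1.50 ± 0.374 CPM against 16.2 ± 5.54 in mensc (SD, n = 3), a log2 fold change of -3.42 ± 0.40 (SE, edgeR adjusted p = 0.0302), and each mensc library, from 11.4 to 22.3 CPM, lay above each library of the other groups. Con, model and gel stood at 4.25 ± 1.11, 4.15 ± 0.795 and 1.94 ± 0.606 CPM (SD, n = 3). With adjusted p from edgeR throughout, the call ended without mensc replicate 1 (0.130) or 2 (0.146) or sp replicate 1 (0.148), 2 (0.298) or 3 (0.201), with no filter on low counts (0.0607) and with only the 6 libraries compared (0.742), while the log2 fold change stayed between -3.68 and -3.17. Without mensc replicate 3 it was kept (0.0333). The adjustment was made within sp vs mensc and not over the 10 comparisons. In the planned test among the 5 groups Doc2b was not called (edgeR adjusted p = 0.0619).

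**Figure D5:**
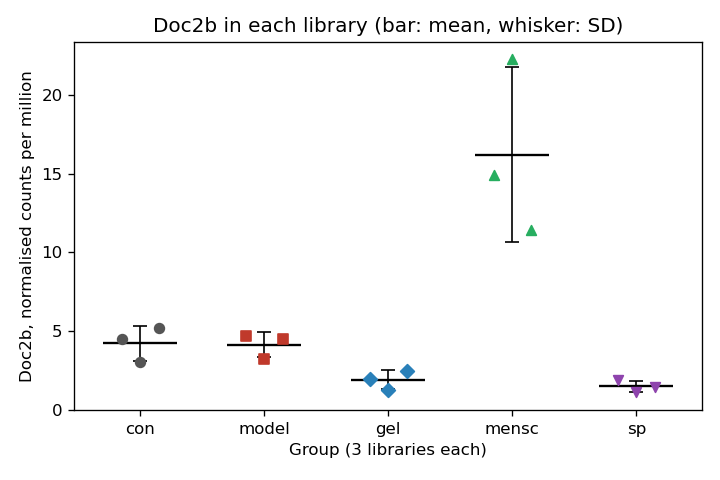
CPM of Doc2b (y axis) in each of the 15 libraries by group (x axis), with the mean as a line and the SD as a bar (n = 3). The 3 mensc libraries lie between 11.4 and 22.3 CPM, and sp averages 1.50 CPM.

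Cell division genes were higher in sp than in mensc in 21 of 21 members, at a mean log2 fold change of 1.43 ± 0.46 (SD over members, camera adjusted p = 1.58e-17; adjusted p = 0.430 with an estimated correlation). Mki67 and Bub1 were at 1.68 ± 0.45 and 1.73 ± 0.45, and Pcna and Mcm4 at 0.83 ± 0.22 and 1.12 ± 0.27 (SE). MHC class II genes were lower in 8 of 8, at -1.53 ± 0.32 (SD over members, adjusted p = 9.65e-07; adjusted p = 0.430 with an estimated correlation), with Ciita at -1.85 ± 0.41, RT1-Bb at -2.20 ± 0.78 and RT1-Ba at -1.91 ± 0.49 (SE). Macrophage genes were lower beside them in 12 of 12, at -1.10 (adjusted p = 0.000681; adjusted p = 0.810 with an estimated correlation), with C1qa at -2.13 ± 0.61 and Cd68 at -1.65 ± 0.39 (SE). Adjusted over the list alone 20 cell division, 8 MHC class II and 2 macrophage members passed, against 0 over all genes in edgeR. DESeq2, without model replicate 2 and over all genes, called 11 of the 21 cell division genes, among them Mki67 at 1.67 ± 0.46 and Ccnb1 at 2.02 ± 0.53 (SE, DESeq2 adjusted p = 0.0365 and 0.0246). It also called Ciita, Cd74, RT1-Ba, C1qa, Cd68, Des, Plin4 and Cxcl6, all lower in sp.

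Also lower in sp than in mensc were smooth muscle at -0.73 (camera adjusted p = 0.0118), B and plasma cells at -1.16 (0.0236) and inflammatory cytokines at -0.76 (0.0493), with 0 members passing adjusted over the list alone. With an estimated correlation the adjusted p was 0.810 for smooth muscle and B and plasma cells and 0.430 for inflammatory cytokines. Camera called 6 lists in sp vs mensc and 5 in the planned fit, and cell division and MHC class II kept their calls without each further library. Without sp replicate 2 the macrophage (-0.59), smooth muscle (-0.06), B and plasma cell (-0.82) and inflammatory (-0.85) calls ended. Those of smooth muscle (-0.78) and inflammatory cytokines (-0.61) ended without mensc replicate 3, which left B and plasma cells at -1.85, and those of B and plasma cells (-0.84) and inflammatory cytokines (-0.69) without mensc replicate 1. B and plasma cells also lost the call without mensc replicate 2 (-0.80) or sp replicate 3 (-0.91), and without sp replicate 1 inflammatory cytokines did (-0.56), with smooth muscle at -1.12 and B and plasma cells at -1.77.

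Doc2b was the 1 gene of 16689 that edgeR called in sp vs mensc, with 1351 at an unadjusted p under 0.05 (2002 without model replicate 2). DESeq2 called 171 on the 15 libraries and 218 without model replicate 2 (103 higher, 115 lower), of which 126 were shared. Chek1, a checkpoint kinase, stood at 12.8 ± 2.60 CPM in sp and 4.52 ± 0.568 in mensc (SD, n = 3), a log2 fold change of 1.50 ± 0.30 (SE, edgeR adjusted p = 0.572). Ppfibp2 was at -1.24 ± 0.23 and Ccdc136 at -1.78 ± 0.33 (SE, both at an edgeR adjusted p of 0.572).

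How far each repaired group stood from sham surgery is addressed by the last 3 comparisons. In gel vs con, cell division genes were higher in 21 of 21 members, at a mean log2 fold change of 1.28 ± 0.50 (SD over members, camera adjusted p = 9.32e-16; adjusted p = 0.730 with an estimated correlation), with Ccne1 at 2.46 ± 0.57 and Foxm1, a mitotic transcription factor, at 1.06 ± 0.30 (SE). Interferon-response genes were lower in 17 of 18, at -0.76 (adjusted p = 7.18e-06; adjusted p = 0.730 with an estimated correlation), with Mx2 at -1.17 ± 0.30 (SE). Mesothelial genes were lower in 7 of 7, at -1.30 (adjusted p = 0.0121; adjusted p = 0.730 with an estimated correlation), and adipose genes higher in 7 of 10, at 1.53 (adjusted p = 0.0424; adjusted p = 0.744 with an estimated correlation). Adjusted over the list alone 15 cell division and 1 interferon-response members passed, against 0 over all genes in edgeR, while DESeq2 called Ccne1. Camera called 4 lists in gel vs con and 4 in the planned fit. Without con replicate 2 the interferon mean was -0.36, the mesothelial call ended without con replicate 3 (-1.50) or gel replicate 1 (-0.91), and the adipose call ended without con replicate 3 (1.22), gel replicate 2 (0.95) or gel replicate 3 (1.45).

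No single gene passed in gel vs con by edgeR, 0 of 16689 with 1058 at an unadjusted p under 0.05 (1641 without model replicate 2). DESeq2 called 25 on the 15 libraries and 23 without model replicate 2. E2f1, a transcription factor of S phase entry, stood at 15.7 ± 7.51 CPM in gel and 5.07 ± 1.14 in con (SD, n = 3), a log2 fold change of 1.63 ± 0.36 (SE, edgeR adjusted p = 0.778). Mme, the peptidase neprilysin, was at -2.22 ± 0.50, Plaat1 at -1.27 ± 0.27 and Iho1 at 5.83 ± 1.07 (SE, each at an edgeR adjusted p of 0.778), with Iho1 at 0.896 CPM in gel replicate 3.

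In mensc vs con, B and plasma cell genes were higher in 9 of 10 members, at a mean log2 fold change of 1.15 ± 0.99 (SD over members, camera adjusted p = 0.000371; adjusted p = 0.532 with an estimated correlation), with Mzb1 at 4.04 ± 1.55 and Cd79b at 1.69 ± 0.81 (SE). Interferon-response genes were lower in 14 of 18, at -0.26 (adjusted p = 0.000371; adjusted p = 0.890 with an estimated correlation), and inflammatory cytokines higher in 13 of 15, at 0.51 (adjusted p = 0.0349; adjusted p = 0.532 with an estimated correlation). Camera called these 3 lists in mensc vs con, and 3 in the planned fit, and 0 members passed adjusted over the list alone or over all genes. The B and plasma cell call ended without con replicate 3 (1.13) and stood at 1.84 without mensc replicate 3. Without con replicate 2 interferon response turned to 0.14, it lost its call without mensc replicate 3 (-0.18) and stood at -0.54 without con replicate 3, while inflammatory cytokines lost theirs without con replicate 1 (0.39) or 2 (0.25) or mensc replicate 1 (0.44) or 3 (0.37) and stood at 0.89 without con replicate 3.

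Single genes in mensc vs con gave 0 calls of 16689 by edgeR, with 125 at an unadjusted p under 0.05 (201 without model replicate 2). DESeq2 called 4 on the 15 libraries and 3 without model replicate 2. The 3 were Doc2b and the uncharacterised loci LOC102549024 and LOC103690146, and the fourth was LOC102547703, all but Doc2b named after their values were seen. Doc2b was at a log2 fold change of 1.93 ± 0.37, Prss12 at 2.01 ± 0.70, Atp2b2, a calcium pump, at -3.89 ± 1.21 and Fam111a at -4.50 ± 1.55 (SE, each at an edgeR adjusted p of 1.00).

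In sp vs con, cell division genes were higher in 21 of 21 members, at a mean log2 fold change of 1.37 ± 0.45 (SD over members, camera adjusted p = 7.26e-18; adjusted p = 0.694 with an estimated correlation), with Aurkb at 1.80 ± 0.50 and Foxm1 at 1.08 ± 0.30 (SE). MHC class II genes were lower in 8 of 8, at -1.38 ± 0.55 (SD over members, adjusted p = 7.90e-06; adjusted p = 0.694 with an estimated correlation), with Ciita at -1.29 ± 0.40 and RT1-Ba at -2.01 ± 0.49 (SE). Macrophage genes were lower beside them in 12 of 12, at -1.06 (adjusted p = 0.00111), smooth muscle genes in 13 of 13, at -0.70 (adjusted p = 0.0142), and interferon-response genes in 14 of 18, at -0.28 (adjusted p = 0.0410). With an estimated correlation the adjusted p was 0.958 for these 3 lists. Adjusted over the list alone 20 cell division and 4 MHC class II members passed and 0 of the other 3 lists, against 0 over all genes in edgeR, while DESeq2 called RT1-Ba. Camera called 5 lists in sp vs con and 4 in the planned fit.

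Cell division and MHC class II kept their calls in sp vs con without each further library. The macrophage and smooth muscle calls ended without con replicate 3 (-0.76 and -0.65) or sp replicate 2 (-0.55 and -0.02), and smooth muscle stood at -1.08 without sp replicate 1. Interferon response turned to 0.12 without con replicate 2, lost its call without con replicate 3 (-0.57) or sp replicate 3 (-0.17) and stood at -0.47 without sp replicate 1. In sp vs con edgeR called 0 of 16689 single genes, with 1046 at an unadjusted p under 0.05 (1602 without model replicate 2). DESeq2 called 63 on the 15 libraries and 51 without model replicate 2. Ccdc136 stood at 23.5 ± 7.47 CPM in sp and 79.2 ± 9.27 in con (SD, n = 3), a log2 fold change of -1.75 ± 0.33 (SE, edgeR adjusted p = 0.778). Ppfibp2 was at -1.14 ± 0.23, Phkg1, a phosphorylase kinase subunit, at -2.07 ± 0.43 and Cyp2d1 at -1.37 ± 0.30 (SE, each at an edgeR adjusted p of 0.778).

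Whether a repair moved genes back toward sham surgery was examined across genes. With 0 genes called by edgeR in model vs con, no set of injury genes could be followed. Across the 17071 genes of the fit without model replicate 2, the log2 fold change of each repair against model correlated with that of model against con at -0.25 for gel, -0.66 for mensc and -0.35 for sp. Both fold changes share the model libraries, and data simulated with no group difference gave -0.60 for each repair. In covariance, which sampling noise shifts by a fixed amount, gel was at -0.0830, mensc at -0.177 and sp at -0.119, against -0.249 in simulated data. The simulation draws each gene independently, while model replicates 1 and 3 lie on opposite sides of the first principal component (25.3 and -45.5). Its value may thus not be the shared term of these data, and the comparison with it cannot decide whether a repair moved genes back. Of 100 regroupings of the libraries, 96, 67 and 85 had a covariance as low as that of gel, mensc and sp. With model replicate 1 used for one fold change and model replicate 3 for the other, in both arrangements, the mean correlation was 0.25 for gel, 0.18 for mensc and 0.22 for sp, and 80, 59 and 67 of 100 regroupings were as low. With all 3 model libraries divided between the fold changes in 6 arrangements, over 12374 genes ahead of the run, it was 0.21 for gel, -0.10 for mensc and 0.13 for sp, and 78, 30 and 63 of 100 regroupings were as low, so the sign for mensc differed between these sets of genes and libraries. These last calculations were chosen after the data were examined, and genes are not independent replicates.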

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

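The counts of splits below were planned, and 1 gene is given because a pair of groups differed in their effect.

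The effects of mensc and sp on Doc2b, each against model, differed by -3.42 on the log2 scale (sp minus mensc, SE 0.40, edgeR adjusted p = 0.0302 for the difference itself, adjusted within this comparison only). Doc2b was higher in 3 of 3 mensc libraries than in any of the 12 other libraries. The call ended without mensc replicate 1 (edgeR adjusted p = 0.130), mensc replicate 2 (0.146), sp replicate 1 (0.148), sp replicate 2 (0.298) or sp replicate 3 (0.201), and its range over all alternatives run in edgeR was 0.00916 to 0.742.

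In sp vs mensc, 2 of the 10 splits of the 6 libraries into 3 and 3 gave at least as many genes as the real one, which gave 1, and the highest other gave 666. That split sets sp replicate 1 and mensc replicates 1 and 2 against the rest, which are the sides of the first principal component, so it points to a structure of the samples. In model vs con the real split gave 0 genes and the highest other 45, for model replicates 1 and 2 and con replicate 3 against the rest, again the sides of the first component. For the other 8 comparisons the real split gave 0 genes. With a real count of 0, 10 of 10 splits give as many by construction there and in model vs con, which says nothing about chance, and the highest other gave 1 in mensc vs gel, 2 in sp vs con and 0 in the other 6. With 10 splits a share under 0.05 cannot be reached. In the test among all 5 groups, the real count was also 0, so that 100 of 100 splits give at least as many by construction, and the highest other gave 1.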

How the results depend on the processing

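The runs without model replicate 2 other than the planned leave-one-out, the surrogate variables, the separate model libraries and the run with genes ahead of the zeros were chosen after the data were examined. Relative log expression size factors and an average log2 CPM of at least 1 left the 11 counts of genes as they were, and an absolute log2 fold change of at least 1 left those of the 10 comparisons. That last setting can only take calls away. The 1 call of the planned fit, Doc2b in sp vs mensc, was at -3.42, so its outcome was fixed in advance. DESeq2 called more genes than edgeR in every comparison on the 15 libraries: 139 among the 5 groups, 2 in model vs con, 6 in gel vs model, 5 in mensc vs model, 10 in sp vs model, 37 in mensc vs gel, 16 in sp vs gel, 171 in sp vs mensc, 25 in gel vs con, 4 in mensc vs con and 63 in sp vs con. Without the truncated library it called 172, 0, 5, 3, 11, 54, 23, 218, 23, 3 and 51 in that order; the cause was not tested. With 2 surrogate variables edgeR called 1 gene among the 5 groups and 1 in mensc vs gel (Doc2b in both) and 2 in sp vs mensc (Doc2b and Il17d, the latter named after its values were seen). With only genes ahead of the run of zeros it called 1 among the 5 groups and 1 in mensc vs gel, again Doc2b. That setting leaves fewer genes tested, 12376, and also takes the zeros out of the fit, and the 2 were not told apart. In sp vs mensc no filter on low counts gave 0 genes and the 6 libraries alone gave 0.

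Leaving out 1 library gave 0 to 1 genes among the 5 groups (Doc2b without model replicate 2, Iho1 without gel replicate 3) and 0 to 1 in sp vs mensc. The correlation of each repair's fold changes with those of the injury, in the fit of 15 libraries, ranged from -0.917 to -0.250 for gel, -0.971 to -0.659 for mensc and -0.927 to -0.351 for sp, in each case weakest without model replicate 2, whose zeros both fold changes share. With separate model libraries for the 2 fold changes, which removes the shared term, it was 0.253 for gel, 0.180 for mensc and 0.221 for sp without model replicate 2, and 0.208, -0.103 and 0.126 with all 3 model libraries and genes ahead of the run, so mensc turned sign. In the planned fit of 15 libraries, 240 list values kept the call under alternatives and 155 lost it. Of these 155, 9 lost it with an average log2 CPM of at least 1. Another 12 turned sign. In sp vs model they were smooth muscle without model replicate 1 (0.35), model replicate 3 (0.27) or sp replicate 2 (0.54), range -1.05 to 0.54, and fibrosis and matrix without model replicate 3 (0.45) or sp replicate 2 (0.43), range -1.14 to 0.45. Macrophage genes there had a mean of 0.02 though camera called them lower, and turned to -1.03 without model replicate 2, -0.14 without sp replicate 1 and -0.33 without sp replicate 3, range -1.03 to 0.67. In sp vs gel, fibrosis and matrix (0.041, range -1.07 to 0.041) and blood (0.011, range -1.69 to 0.011) turned without sp replicate 2. Interferon response turned without con replicate 2 in mensc vs con (0.16, range -0.54 to 0.16) and sp vs con (0.11, range -0.56 to 0.11). For named genes 0 values turned sign, 526 kept their side of the threshold, 51 passed it, 25 of them in DESeq2 on the 15 libraries and 24 in DESeq2 without model replicate 2, and 7, all of Doc2b in sp vs mensc, lost it. No paired analysis was possible because the labels give no replicate numbers shared between groups. Depth limits what can be said of genes with few counts.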

Other observations

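The genes in the first 2 paragraphs were picked after their values were seen. The tests at equal depth were planned before their result was seen, and the tests of the run of zeros and of the gene lists on the components were chosen after it.

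Retnlg, Ccr3 and Il5ra, the last a subunit of the receptor for interleukin 5 on eosinophils, varied from library to library within groups. Retnlg stood at 481, 124 and 0.962 CPM in gel replicates 3, 1 and 2 and at 317, 3.09 and 0.899 CPM in mensc replicates 2, 1 and 3. Ccr3, the eotaxin receptor, stood at 114, 26.1 and 0.453 CPM and at 75.3, 1.50 and 0.484 CPM in the same libraries. Ifit1, an interferon-induced gene, stood at 77.3 CPM in con replicate 2 and 0 in con replicate 3, and at 116 CPM in sp replicate 1.

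C3, Lpo and Tmprss4 were lower in sp replicate 1 than in each of the other 14 libraries. C3, a complement component, stood at 36.8 CPM there and at 1712 to 10541 CPM elsewhere. Lpo, lactoperoxidase, stood at 0.111 CPM against 81.3 to 955 CPM. Tmprss4, a membrane protease, stood at 0 against 5.97 to 94.2 CPM. The epithelial list score of sp replicate 1, -1.47, was also the lowest of the 14 libraries scored.

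In model replicate 2, the run of zeros to the end of the table was weighed first. Too few reads are argued against, since Col6a1, at a mean of 81444.5 counts in the other 14 libraries, is among the genes at 0. Loss of expression after injury is argued against too, since 3782 of the 3788 expressed genes in the run have reads in both other model libraries. What stays open is that the counts of this library stop at 1 place in the table's order, since 100% of expressed genes are at 0 from there on, so its deposited column may be incomplete.

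Libraries of one group lay on both sides of the first principal component. Unequal depth is argued against, since 15 of 15 libraries kept their side after all were thinned to 11383123 counts. Oestrogen exposure may have differed between the samples, since the mean loading of the oestrogen-responsive list lay at percentile 99.99 of random lists, with 10 of 11 members positive, though cell division and squamous genes, both at percentile 100, lay further out. The share of epithelium in the pieces may have differed as well, since the epithelial list also lay at percentile 99.99, with fibrosis and matrix, macrophage, mesothelial, T and NK cell and smooth muscle lists at 0, 0.32, 0.17, 1.31 and 2.14, though stroma (15.5), endothelium (3.14), B and plasma cells (11.5), adipose tissue (47.8), blood (49.7), eosinophils and mast cells (75.6), neutrophils (88.7), skeletal muscle (86.2) and ciliated epithelium (28.0) did not lie beyond 2.5, so shares of tissue alone leave part of it open. Both stay open as hypotheses found and tested on the same data, and no biological explanation from the design was tested, since con, model, mensc and sp each lie on both sides and only gel lies wholly on one. The random lists were drawn gene by gene, so a list whose genes vary together can lie far out whatever its theme. Interferon-response genes (0.35) and inflammatory cytokines (98.25) lay far out too. The percentiles thus cannot decide for either hypothesis.

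Sp replicate 2 stood apart on the second component. Unequal depth is argued against, since its score was 76.5 after thinning to equal depth. Even dilution of all other cell types by epithelium is argued against, since smooth muscle genes lay below endothelial genes by a further -0.96 ± 0.24 (log2, SE over list members in this library). That SE treats genes as independent and does not measure the spread between libraries. Among the other 13 libraries smooth muscle lay furthest below endothelium in gel replicate 2, with list scores of -0.01 and 0.34, against -1.97 and -1.08 in sp replicate 2. The piece sequenced may have held unequal shares of the uterus's layers: epithelial genes had a median of 1.58 above the other 13 libraries, and the highest of 8 lists (stroma, smooth muscle, endothelium, macrophage, T and NK, B and plasma cells, mesothelium, adipose tissue) had -1.06, while cell division genes (1.50) and hypoxia and glycolysis genes (0.76) lay above too. Krt8, an epithelial keratin, stood at 3604 CPM there against 134 to 2310 CPM in the others, and Myh11, smooth muscle myosin, at 964 against 3211 to 5866 CPM. But Prom1 (epithelium, 1402 against 119 to 1715 CPM) and Col6a3 (stroma, 1225 against 551 to 6078 CPM) lay within the range of the others. Sp replicates 1 and 3 do not share the pattern. Sp replicate 1 had the lowest epithelial list score of the 14 libraries scored, -1.47, and sp replicate 2 the highest, 1.54, with sp replicate 3 at 0.04. No biological explanation from the design was tested.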
